A study of Homo sapiens with 6 samples.

How the data were processed

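RNA from the center and the periphery of xenograft tumors of 3 mice was hybridized to 6 arrays, 1 per sample. Per the labels' protocols, total RNA was purified on columns with DNase treatment and biotin-labeled by the Affymetrix method with a single amplification cycle. The deposited values are signal intensities, 1 per probe set and array, on a linear scale. Per the submitters' processing notes these values were made with MAS5, which summarizes the probe pairs of a probe set after subtracting mismatch signal; its version is not given in the sources used here. From the values themselves, each array had been scaled to a 2% trimmed mean of about 250, so no further scaling was applied. Such scaling removes differences in total signal, and an array with weak labeled RNA then shows raised background and raised spike-in signal. Detection calls and scanner files were not used here, so no probe set was judged present or absent, and 0 columns of per-sample values were left unused.

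Of 54675 probe sets, 62 controls were left out of the gene tests. In the platform annotation, 41091 of the others carried 1 gene symbol, 1801 carried several and 11721 were not listed, and only those with 1 symbol were used. Symbols were checked by gene identifier against the RefSeq table of the GRCh38 assembly, which matched 41037 of these probe sets and changed 0 symbols; no coordinates were taken from it. For each of 19775 genes the probe set with the highest mean log2 signal over the 6 arrays was kept. Genes with a mean below 6.69 on the log2 scale, the median of all probe sets, were left out, and 12849 genes remained. Of 70 named genes, 34 had more than 1 probe set above the filter and 5 of these had a probe set of opposite sign.

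Signals were tested as log2(signal + 16), and each log2 difference and fold is on that scale, which understates the change of dim genes. The test was limma's lmFit and eBayes, two-sided, on the 6 arrays with mouse as a block, adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Differences are center minus periphery, given with the standard error from this fit, and levels are mean signals ± SD over 3 arrays. The pairs come from the sample titles and the design text, which place both samples of a number in the same animal; over all genes the deviations of paired samples from their group means correlated at 0.19, -0.08 and 0.05 in mice 1, 2 and 3. The replicates are tumors of separate mice.

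The tests, the filter, the pseudocount, the rule for naming genes, most alternative settings and 40 gene lists were fixed before the data were examined. The lists covered oxygen and energy metabolism, the cell cycle, invasion, growth signals, stress, inflammation, protein and lipid synthesis, epithelial markers and markers of other cell types. The 35 lists with at least 4 tested members were tested against all other genes with limma's camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry, which asks whether the genes of a list move without comparing them with others. The camera test with an estimated correlation rests on the 2 residual degrees of freedom of the fit. Named genes were, per direction and among genes of 1 sign in 3 of 3 mice, the 12 with the largest difference past the threshold, with places left open filled by the smallest p. Since 0 genes passed, all 24 were filled in this way. The rule added the 3 members with the smallest p of each list that passed camera, the brightest member of each marker list, and a short fixed set of genes of oxygen response, growth and invasion, of which those reported passed the filter. It left out immunoglobulin genes and uncharacterized transcripts.

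RNA quality was read from the 3' and 5' control probe sets of ACTB and GAPDH, with an exact two-sided sign-flip test over the 3 mice. Spike-in signal was the mean log2 signal of 18 control probe sets. The gene test was tested on simulated data for the comparison of center with periphery over 12849 genes. It called 4% of 50 genes changed by a log2 of 1 and 70% of 50 changed by 2. It called 94% of 50 changed by 3, 100% of 49 changed by 4, and 9 unchanged genes. All these genes changed in 1 run, and the adjusted threshold eases as more genes change. These rates therefore need not hold where fewer genes change. In the same simulation a shift of -0.5 on the log2 scale in the 25 mitosis genes gave a camera adjusted p of 2.06e-13. There 0 of the other lists were called, and the adjusted p of camera with an estimated correlation was 0.453. The simulated noise was independent between genes, so this run could not show false calls that arise from correlated genes. In the data the estimated correlation within a list reached 0.776 (cytosolic ribosomal proteins).

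Alternatives changed the pseudocount, the filter, the scaling (quantile normalization, median centring), the block, the summary over probe sets and the variance prior, or left out each mouse in turn. Array weights and fits without the arrays of high spike-in signal were added after the data had been seen. All 10 ways of splitting the 6 arrays into 3 and 3 were also tested. The work used R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.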

Results

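Gene expression was measured on Affymetrix oligonucleotide arrays in xenografts of a human pancreatic carcinoma carried in the pancreas of nude mice, which lack a thymus and accept human tissue. From the tumor of each of 3 mice, 1 sample came from the center and 1 from the periphery, giving 3 center and 3 periphery arrays. The comparison asked how expression differed between these zones of the same tumor. The arrays carry probes for human transcripts, and the tissue can also hold mouse cells, whose transcripts were not separated from human ones here. Every array had a trimmed mean signal of about 250, and median signals lay between 84.7 and 125. The number of arrays limits the precision of each value.

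The arrays differed in spike-in signal and in the 3' to 5' signal ratio of ACTB. The bacterial spike-in controls, added to each sample in fixed amounts, read lowest on periphery 1, and the other arrays lay above it by 1.55-fold (periphery 3), 1.89-fold (center 2), 2.05-fold (center 1), 5.63-fold (center 3) and 14.2-fold (periphery 2). Periphery 2 also stood apart in its correlation with the other arrays across genes, with r from 0.87 to 0.89, whereas each other array reached an r of 0.939 to 0.964 with its nearest neighbour. The ACTB 3' to 5' signal ratio, which rises as RNA is degraded, averaged 56.6 ± 12.6 in the center and 33 ± 14.9 in the periphery (SD, n = 3). This ratio was far above 1 on every array, from 23.5 (periphery 3) to 68.4 (center 2), so intact RNA was shown in neither zone. It was higher in the center of 3 of 3 mice, by a mean log2 difference of 0.84 ± 0.43 (SD, n = 3; two-sided exact sign-flip permutation test, p = 0.25, the smallest that 3 pairs allow). The GAPDH ratio was 8.25 ± 2.82 in the center and 7.73 ± 3.58 in the periphery, and was higher in the center of 1 of 3 mice (exact p = 1).

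**Figure D1:**
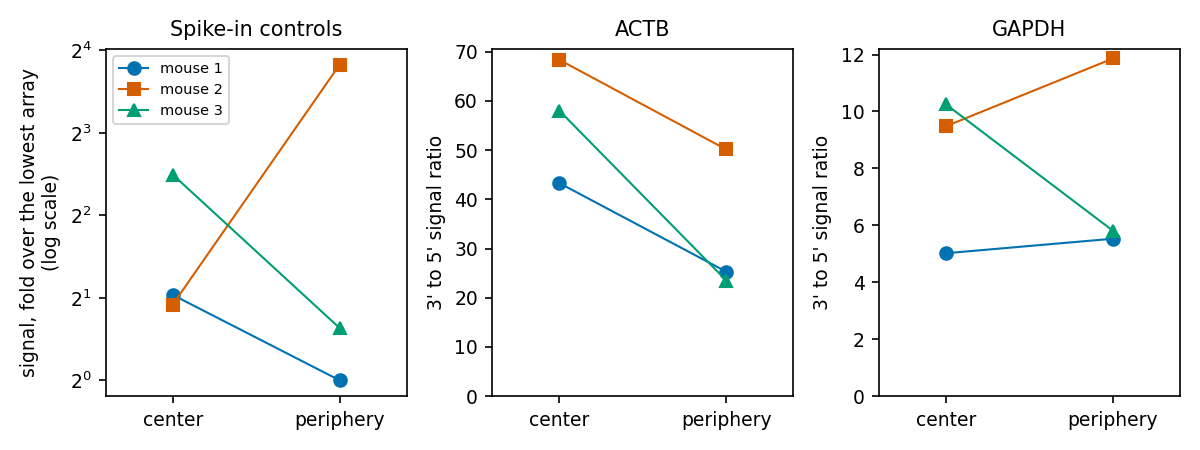
Signal of the spike-in controls (fold over the lowest array, log scale) and 3' to 5' signal ratios of ACTB and GAPDH on the 6 arrays, with a line joining center and periphery of each mouse. Periphery 2 had the highest spike-in signal, 14.2-fold over the lowest array, and the ACTB ratio was higher in the center of 3 of 3 mice.

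The 12 genes named as higher in the center included a chemokine receptor, connexins and S100 proteins. ACKR3, a scavenger receptor for the chemokine CXCL12, had a mean signal of 2572 ± 814 in the center and 252 ± 26 in the periphery (SD, n = 3), a log2 difference of 3.23 ± 0.26 (SE). The gap junction genes GJB6 and GJB2 differed by 3.87 ± 0.37 and 2.19 ± 0.24, with GJB6 at 462 ± 265 against 12.2 ± 3.17. That periphery signal lay below the pseudocount of 16, so the size of the GJB6 difference is set largely by the pseudocount (2.62 with a pseudocount of 64). S100A7 and S100A8, calcium-binding proteins of inflamed epithelium, differed by 3.01 ± 0.25 and 2.95 ± 0.31. IGFBP3, which binds insulin-like growth factors and was the brightest gene of this group at 28304 ± 4789 against 5802 ± 1398, differed by 2.30 ± 0.23. The other genes named were VMO1 (2.93 ± 0.26), NPTX1 (2.63 ± 0.25), SIX5 (2.51 ± 0.27), RARRES1 (2.46 ± 0.26), CYP24A1, which inactivates vitamin D (2.16 ± 0.23), and the noncoding NUP133-DT (2.10 ± 0.24). All 12 were higher in 3 of 3 mice, with limma adjusted p from 0.0628 to 0.0735, so none passed the threshold of 0.05. A further probe set of ACKR3, VMO1 and S100A8 differed less, by 0.73, 0.67 and 1.70. Periphery signals were also low for S100A7 (28 ± 5.86), NUP133-DT (36 ± 2.98) and SIX5 (43.4 ± 22). The sizes of these 3 differences therefore depend in part on the pseudocount.

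The genes named on the opposite side were lower in the center and included matrix and cytoskeletal genes. COL1A2, a chain of type I collagen, had a mean signal of 164 ± 11.2 in the center and 919 ± 21.7 in the periphery, a log2 difference of -2.38 ± 0.22. The matrix and basement membrane genes TGFBI, NID2 and EFEMP1 differed by -1.91 ± 0.23, -1.69 ± 0.23 and -1.61 ± 0.22. AMIGO2 and the cadherin CDH11, both cell adhesion molecules, differed by -2.25 ± 0.23 and -1.95 ± 0.28, although another CDH11 probe set gave -0.08. MAP1B, TUBA1A and KIFC1, a microtubule-associated protein, a tubulin and a mitotic kinesin, differed by -1.67 ± 0.23, -1.72 ± 0.25 and -1.83 ± 0.25. The ductal keratin KRT7 stood at 1324 ± 372 against 4399 ± 1303 and differed by -1.72 ± 0.24 (weakest probe set -0.94), and KCNMA1 and MLLT11 by -1.60 ± 0.24 and -1.67 ± 0.26. All 12 were lower in 3 of 3 mice, with adjusted p from 0.0628 to 0.139. At an adjusted p below 0.1 there were 14 genes higher and 4 lower in the center, the latter being COL1A2, AMIGO2, TGFBI and an immunoglobulin gene, a kind left out by the naming rule.

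Of 12849 genes tested with limma and mouse as a block, 0 were higher and 0 lower in the center at an adjusted p below 0.05, and the smallest adjusted p was 0.0628. At an unadjusted p below 0.05, 748 genes were higher and 637 lower, against 642 expected in all if no gene differed. The sign was the same in 3 of 3 mice for 35% of genes (2243 higher and 2259 lower), where chance gives 25%, and 75 genes were higher and 43 lower by over 1 log2 in each mouse. The blocked fit had 2 residual degrees of freedom, and the fit with no replicate block called 38 genes higher and 17 lower. Without mouse 1 the blocked fit called 12 higher and 0 lower, without mouse 2 it called 0 in either direction, and without mouse 3 it called 9 higher and 1 lower.

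**Figure D2:**
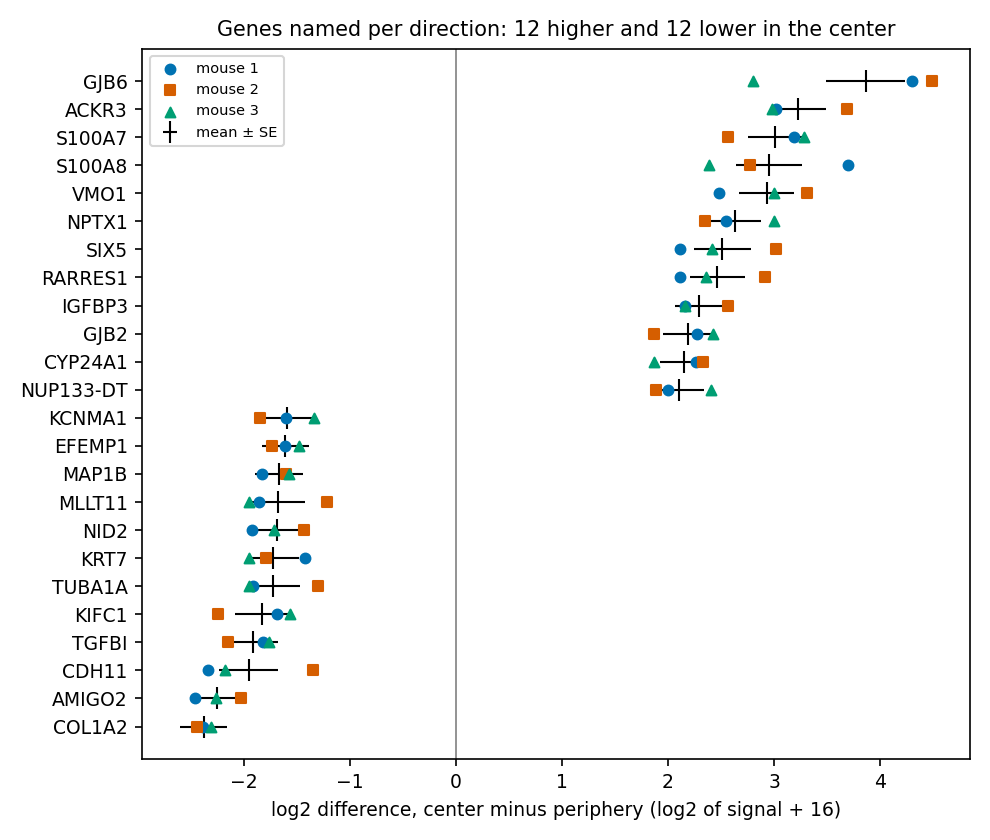
Log2 difference, center minus periphery, of the 12 genes named in each direction; colored symbols are the 3 mice and black bars the mean ± SE. All 24 genes had the same sign in 3 of 3 mice, and the smallest adjusted p was 0.0628.

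Of 40 gene lists, 35 had at least 4 tested members; by limma's camera 6 were shifted upward and 5 downward in the center at an adjusted p below 0.05. Those shifted upward held hypoxia-inducible genes, glycolysis enzymes, cytosolic ribosomal proteins, keratinocyte differentiation genes, NF-kappaB cytokines and chemokines, and pancreatic cancer mucins. Those shifted downward held proteasome subunits, mitosis genes, DNA replication genes, cholesterol synthesis enzymes and mesenchymal transition genes. Camera set the correlation between genes at 0.01, and with an estimated correlation 0 of the 35 lists passed. That version also missed a simulated shift of -0.5 in the mitosis list (camera with an estimated correlation, adjusted p = 0.453), so its values decide little either way. The directional fry test also passed 0 lists. Without mouse 3, the lists shifted downward numbered 3.

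**Figure D3:**
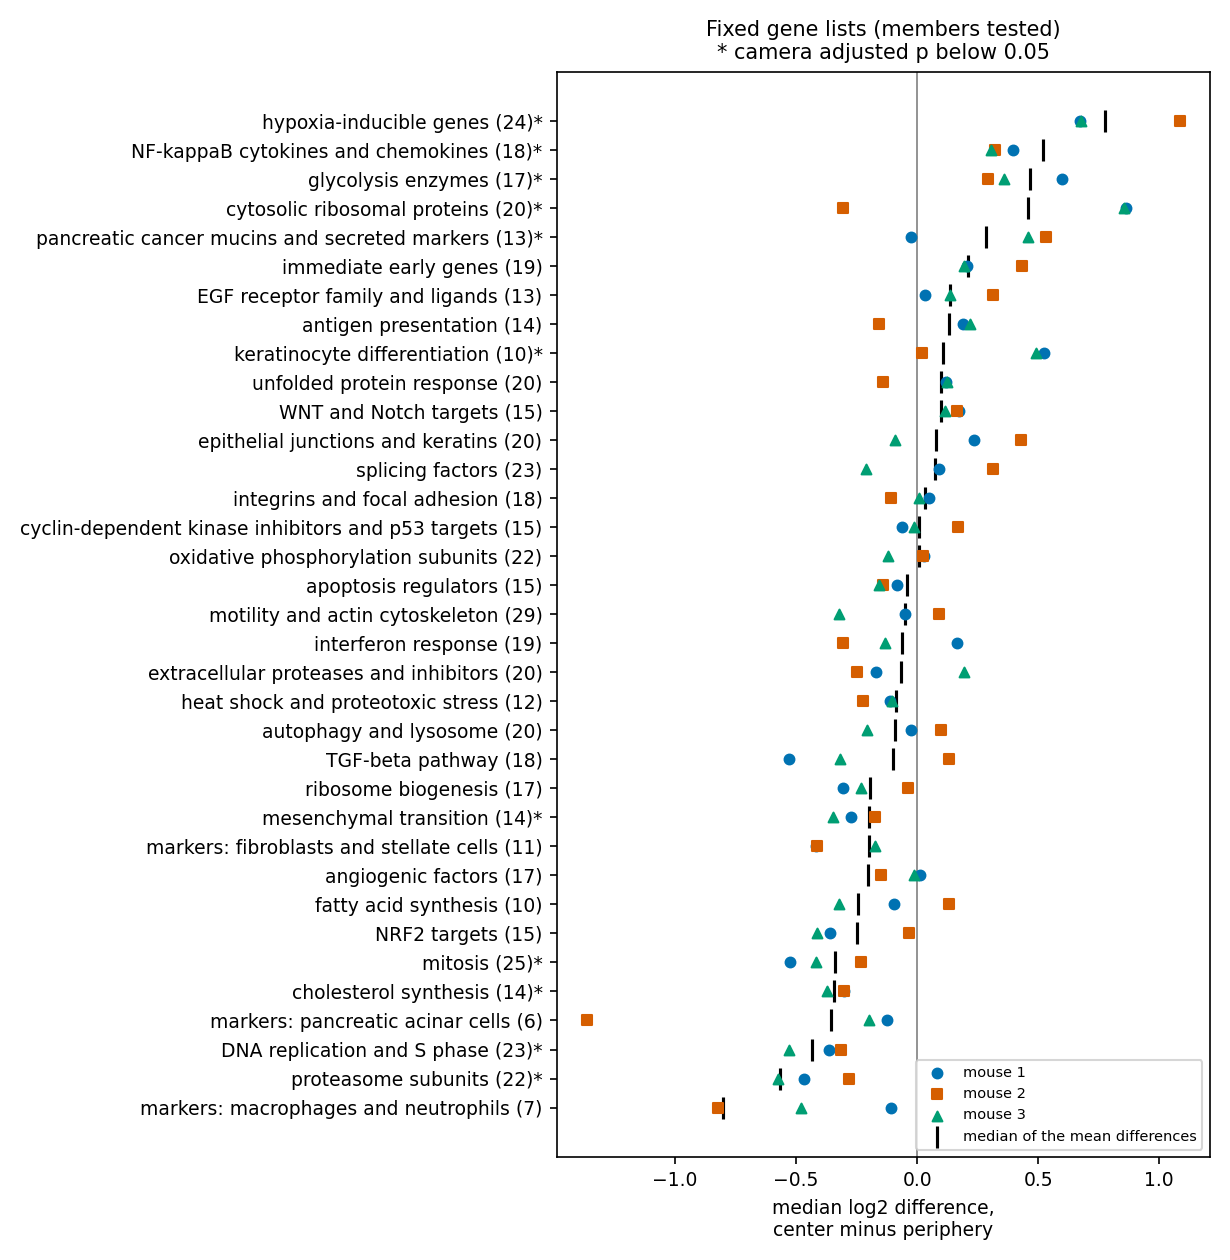
Median log2 difference, center minus periphery, of each of the 35 tested gene lists in each mouse (colored symbols) and over the mean differences (black bars), with the number of tested members in parentheses and an asterisk where camera passed. Hypoxia-inducible genes had the highest median, 0.78, and their medians were above 0 in 3 of 3 mice.

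Genes induced by low oxygen were shifted upward in the center as a list. Of 24 hypoxia-inducible genes tested, 20 were higher in 3 of 3 mice and 0 were lower in 3 of 3, and the list had a median log2 difference of 0.78, with 0.67, 1.09 and 0.68 in mice 1, 2 and 3. LOX, which cross-links collagen, differed by 1.68 ± 0.23 (2108 ± 93.6 against 646 ± 55.4), NDRG1 by 1.64 ± 0.26 and the mitophagy receptor BNIP3L by 1.44 ± 0.22. The glucose transporter SLC2A1 differed by 1.11 ± 0.26 and the angiogenic factor VEGFA by 0.62 ± 0.22, with other probe sets as low as 0.71 for BNIP3L, 0.47 for SLC2A1 and 0.27 for VEGFA. The list passed camera (adjusted p = 2.43e-14; adjusted p = 0.544 with an estimated correlation), and 11 members were higher when adjusted over the list alone, against 0 over all genes tested. The ACTB 3' to 5' ratio was higher in the center of the same 3 mice, by 0.84 on the log2 scale.

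**Figure D4:**
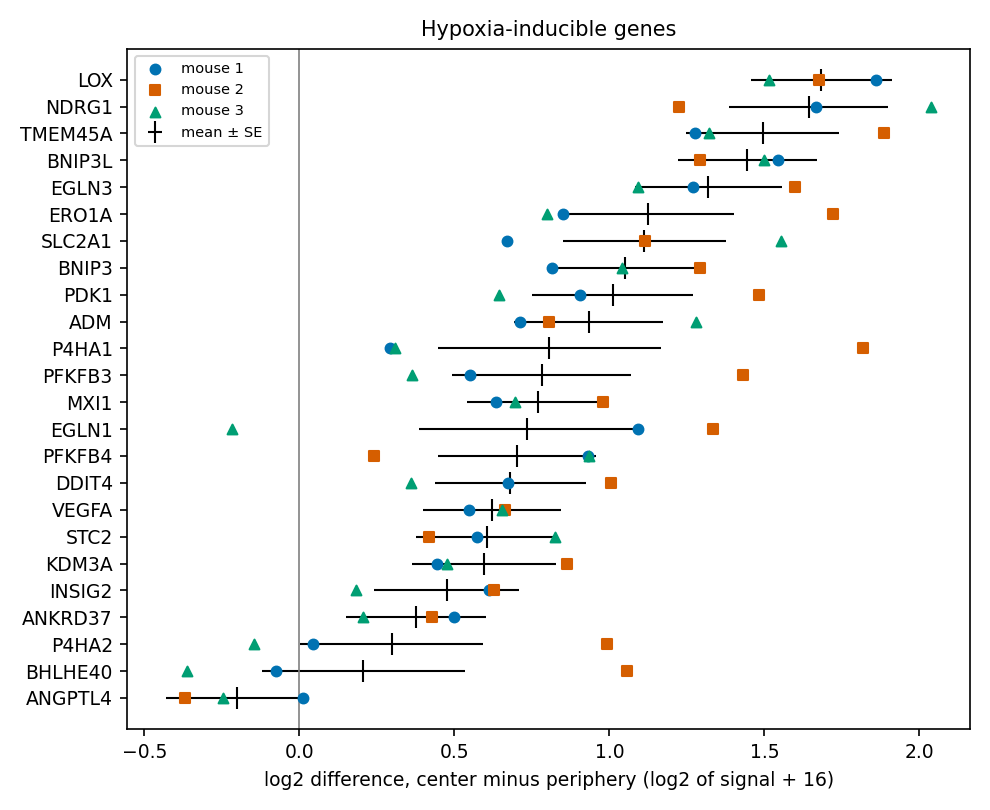
Log2 difference, center minus periphery, of the 24 tested hypoxia-inducible genes; colored symbols are the 3 mice and black bars the mean ± SE. Of these genes, 20 were higher in the center of 3 of 3 mice.

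Glycolysis enzymes were also shifted upward, with a median of 0.47 and 10 of 17 members higher in 3 of 3 mice against 1 lower. The glucose transporter SLC2A3 differed by 0.96 ± 0.24 (lowest probe set 0.33), ENO2 by 0.88 ± 0.23 and HK2, which phosphorylates glucose, by 0.81 ± 0.22, although both other HK2 probe sets had the opposite sign (lowest -0.74). The list passed camera (adjusted p = 0.000187; adjusted p = 0.544 with an estimated correlation), with 0 members called over the list alone. Leaving out probe sets with the suffix _x_at or _s_at ended the call (median 0.295, adjusted p = 0.0858). The list medians of 0.60, 0.29 and 0.36 in mice 1, 2 and 3 were above 0 in 3 of 3 mice. The ACTB ratio differences were too, so these signs cannot tell RNA integrity from zone. The bright members GAPDH (0.71, -0.05 and 1.15) and LDHA (0.68, 0.03 and 0.85) were lowest in mouse 2. Spike-in signal and the 80 brightest genes other than ribosomal protein genes were lowest there too. Glycolysis genes were not removed from those 80, so the set can hold these same members. The bright PGK1, PGAM1 and ENO1 were also lowest in mouse 2, but TPI1 (0.60, 0.66 and 0.36) and ALDOA (0.72, 0.57 and 0.10) were lowest in mouse 3. The 22 tested subunits of oxidative phosphorylation, the mitochondrial route to ATP, had a median of 0.01 and a mean of -0.02 (adjusted p = 0.857).

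Genes of the cell cycle were shifted downward in the center. Of 23 DNA replication genes, 14 were lower in 3 of 3 mice and 0 higher, with a median of -0.44; GINS2 of the replicative helicase differed by -1.08 ± 0.22, the licensing factor CDT1 by -0.92 ± 0.27 and MCM7 by -0.81 ± 0.25, while another probe set gave -0.24 for GINS2 and -0.02 for MCM7. Of 25 mitosis genes, 19 were lower in 3 of 3 mice and 0 higher, with a median of -0.34; BIRC5 differed by -0.73 ± 0.22, CDC20 by -0.73 ± 0.23 and KIF23 by -0.67 ± 0.23, while another probe set gave 0.09 for KIF23 and 0.002 for BIRC5. MKI67, the gene of the proliferation marker Ki-67, differed by -0.19 ± 0.22 (634 ± 49.7 against 724 ± 15.6). Its 3 other probe sets were also lower, down to -0.41. Both lists passed camera (adjusted p = 1.86e-05 for replication and 9.83e-06 for mitosis; each adjusted p = 0.544 with an estimated correlation), and 0 members of either were called over the list alone. Both medians had the same sign in 3 of 3 mice, as did the ACTB 3' to 5' ratio, so these signs cannot tell RNA integrity from zone. The replication medians (-0.36, -0.32 and -0.53 in mice 1, 2 and 3) had the order of the ACTB log2 differences (0.78, 0.45 and 1.30). The GAPDH ratio and spike-in differences had that order too. The mitosis medians (-0.525, -0.23 and -0.42) did not, being largest in size in mouse 1.

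Proteasome subunits, which form the protease that degrades ubiquitin-tagged proteins, were shifted downward, with 17 of 22 lower in 3 of 3 mice, 0 higher and a median of -0.57. PSMD11 differed by -0.97 ± 0.27 (another probe set -0.30), PSMD2 by -0.65 ± 0.22 and PSMC3 by -0.83 ± 0.33 (camera adjusted p = 1.73e-07; adjusted p = 0.544 with an estimated correlation). The proteasome medians of -0.47, -0.28 and -0.58 in mice 1, 2 and 3 had the order of the log2 differences of the ACTB 3' to 5' ratio, which were 0.78, 0.45 and 1.30. The GAPDH ratio (-0.14, -0.32 and 0.82) and spike-in signal (1.04, -2.91 and 1.86) differed in the same order. An order of 3 values also matches easily by chance, so it does not single out RNA integrity. Cholesterol synthesis enzymes had a median of -0.34 and 8 of 14 lower in 3 of 3 mice, with list medians of -0.30, -0.30 and -0.37 in mice 1, 2 and 3; SQLE differed by -0.99 ± 0.28, HMGCS1 by -0.57 ± 0.22 and NSDHL by -0.64 ± 0.26, with other probe sets of SQLE and HMGCS1 as weak as -0.18 and -0.12. This list also passed (adjusted p = 0.0114; adjusted p = 0.544 with an estimated correlation), but not without mouse 1 (median -0.34, adjusted p = 0.0535) or mouse 3 (median -0.305, adjusted p = 0.101). In both lists 0 members were called over the list alone. Fatty acid synthesis enzymes (10 tested, median -0.24) and NRF2 targets, which counter oxidative stress (15 tested, median -0.25), did not pass (adjusted p = 0.1 for each). NRF2 targets passed in 5 alternative settings (adjusted p from 0.00844 to 0.0379) and fatty acid synthesis in 3, among them the fit without mouse 2 (adjusted p from 0.0235 to 0.0345), all downward.

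Cytosolic ribosomal proteins had a median of 0.46 but moved apart between mice, at 0.86 in mouse 1, -0.31 in mouse 2 and 0.85 in mouse 3, and 6 of 20 were higher in 3 of 3 mice. RPL6 differed by 0.68 ± 0.24, RPL8 by 0.65 ± 0.27 and RPL30 by 0.57 ± 0.24. The list passed camera (adjusted p = 5.64e-05; adjusted p = 0.634 with an estimated correlation), and 0 members were called over the list alone. Spike-in signal differed in the same directions, by a log2 of 1.04, -2.91 and 1.86 in mice 1, 2 and 3. So did the median of the 80 brightest genes other than ribosomal protein genes, at 0.54, -0.22 and 0.56. Camera's call ended under quantile normalization (median 0.11, adjusted p = 0.261), without mouse 1 (median 0.30, adjusted p = 0.0729) and without _x_at and _s_at probe sets (median 0.36, adjusted p = 0.0886). The 17 tested ribosome biogenesis genes had a median of -0.19 (adjusted p = 0.226), and the 23 splicing factors one of 0.08 (adjusted p = 0.787).

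Pancreatic cancer mucins and secreted markers were shifted upward as a list. Among the 13 tested, the membrane mucins MUC4 and MUC1 differed by 2.34 ± 0.27 (1786 ± 396 against 344 ± 103) and 2.26 ± 0.29, and S100P by 0.90 ± 0.24; these 3 were called when adjusted over the list alone, and the 5 MUC4 probe sets ranged from 0.08 to 2.34 and the 3 of MUC1 from 0.70 to 2.26. In all, 4 members were higher and 2 lower in 3 of 3 mice, with list medians of -0.03, 0.53 and 0.46 in mice 1, 2 and 3 (camera adjusted p = 0.0249; adjusted p = 0.544 with an estimated correlation). The call ended without mouse 2 (adjusted p = 0.188), without _x_at and _s_at probe sets (adjusted p = 0.169), with array weights (adjusted p = 0.174), and with no replicate block once periphery 2 (adjusted p = 0.0729) or the 2 arrays with the highest spike-in signal (adjusted p = 0.158) were left out, with medians from 0.055 to 0.226 over these settings. Of 10 keratinocyte differentiation genes, 5 were higher in 3 of 3 mice; the median was 0.11 and the mean 0.90, since the S100 proteins S100A7, S100A8 and S100A9 (2.39 ± 0.31) led the list. List medians were 0.52, 0.02 (SE 0.61) and 0.49 in mice 1, 2 and 3, with an error too wide to rank mouse 2. Of the leading genes, S100A7 (3.19, 2.57 and 3.29) was lowest in mouse 2, as was spike-in signal. S100A8 (3.70, 2.77 and 2.39) and S100A9 (3.01, 2.50 and 1.67) were lowest in mouse 3. S100A8 and S100A9 are also abundant in neutrophils. This list passed camera (adjusted p = 0.002; adjusted p = 0.634 with an estimated correlation), with 4 members called over the list alone, but not with dim genes kept (median 0.03, adjusted p = 0.0573). Epithelial junction genes and keratins (20 tested, median 0.08) did not pass (adjusted p = 0.232), although CDH1, the gene of E-cadherin, differed by 1.10 ± 0.27 and KRT7 was the 1 member called over the list alone.

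NF-kappaB cytokines and chemokines were shifted upward, with a median of 0.52 and 10 of 18 higher in 3 of 3 mice against 2 lower. The chemokine CCL20 differed by 2.40 ± 0.41 (5094 ± 956 against 1108 ± 651) and was the 1 member called over the list alone. NFKBIA, an inhibitor of NF-kappaB, differed by 0.66 ± 0.22 and CXCL8 by 0.65 ± 0.31. IL1B differed by -0.64 ± 0.25 (another probe set -1.29). List medians were 0.39, 0.32 and 0.305 in mice 1, 2 and 3. Like the ACTB ratio differences they were above 0 in 3 of 3 mice, so these signs cannot tell RNA integrity from zone. The list passed camera (adjusted p = 0.00354; adjusted p = 0.544 with an estimated correlation), but not without _x_at and _s_at probe sets (median 0.24, adjusted p = 0.324). Interferon response genes (19 tested, median -0.06, mean 0.05, adjusted p = 0.704) and antigen presentation genes (14 tested, median 0.13, adjusted p = 0.293) did not pass.

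Mesenchymal transition genes were shifted downward, with 6 of 14 lower in 3 of 3 mice and a median of -0.20. The matrix protein gene FN1 differed by -1.28 ± 0.23, S100A4 by -1.46 ± 0.27 and MMP2, a gelatinase, by -1.15 ± 0.22, and these 3 were lower when adjusted over the list alone; another MMP2 probe set gave 0.04. LOX, also a hypoxia-inducible gene, was the 1 member higher in 3 of 3 mice and was called over the list alone. The list passed camera (adjusted p = 0.0325; adjusted p = 0.544 with an estimated correlation), but not with no replicate block (median -0.20, adjusted p = 0.052), without mouse 1 (median -0.22, adjusted p = 0.162) or without mouse 3 (median -0.345, adjusted p = 0.101). It also missed the threshold with the upper-quartile filter, the mean of all probe sets and the exclusion of _x_at and _s_at probe sets (medians from -0.342 to -0.198, adjusted p from 0.0619 to 0.0846). Lower signals were also measured in the center for the fibroblast and macrophage markers COL1A2 (-2.38), COL3A1 (-1.86), PDGFRA (-0.92) and CSF1R (-0.80). LUM was higher and COL1A1 differed by -0.05. Of 18 such markers tested, 8 were lower in 3 of 3 mice, 3 higher in 3 of 3 and 7 mixed. The medians of the mesenchymal list, -0.27, -0.17 and -0.35 in mice 1, 2 and 3, had the order of the ACTB ratio differences (0.78, 0.45 and 1.30). The GAPDH ratio and spike-in differences had the same order, so it does not single out RNA integrity.

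Markers of other cell types did not pass camera but held members on both sides. Of 11 fibroblast and stellate cell markers (median -0.20, adjusted p = 0.1), COL1A2, COL3A1 (-1.86 ± 0.29) and PDGFRA (-0.92 ± 0.22) were lower and LUM (1.58 ± 0.38) higher when adjusted over the list alone. COL1A1, the brightest of them, stood at 5712 ± 1168 against 5873 ± 945 and differed by -0.05 ± 0.27, while its 3 other probe sets were also lower, down to -0.74. Of 7 macrophage and neutrophil markers (median -0.80, adjusted p = 0.0549), CSF1R (-0.80 ± 0.22) and FCER1G (-0.84 ± 0.24) were lower over the list alone, and the brightest, CD53, differed by -0.99 ± 0.45. The 6 acinar cell markers had medians of -0.12, -1.37 and -0.20 in mice 1, 2 and 3 (adjusted p = 0.141), and the brightest, CTRC, differed by 0.12 ± 0.49. In some alternative settings these lists passed as lower: macrophage markers without mouse 1 (adjusted p = 0.00583), with a pseudocount of 64 (0.0473) and with median centring (0.0462), acinar markers without mouse 1 (0.0174) and fibroblast markers with the upper-quartile filter (0.0124). Lists with under 4 tested members were given no list test: endothelial (3 tested, PECAM1 0.27 ± 0.23), erythroid (3 tested, HBB -0.65 ± 0.27), smooth and skeletal muscle (3 tested, ACTG2 -1.29 ± 0.29), adipocyte (2 tested, CIDEC 0.11 ± 0.26) and islet cell markers (1 tested, SST -0.11 ± 0.33).

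The remaining lists did not pass camera. Angiogenic factors (17 tested) had a median of -0.20 (adjusted p = 0.486), TGF-beta pathway genes (18 tested) one of -0.10 (adjusted p = 0.232) and extracellular proteases and inhibitors (20 tested) one of -0.07 (adjusted p = 0.669), with MMP9 at -0.39 ± 0.33. Motility and actin genes (29 tested) had a median of -0.05 (adjusted p = 0.293; 0.0337, downward, with the mean of all probe sets). Integrin and focal adhesion genes (18 tested) had a median of 0.03 and a mean of -0.01 (adjusted p = 0.973). EGF receptor family genes and ligands (13 tested) had a median of 0.14 and a mean of -0.01 (adjusted p = 0.576), and EGFR itself, whose probe sets ranged from -0.81 to 0.61, differed by 0.16 ± 0.39. WNT and Notch targets (15 tested) had a median of 0.10 (adjusted p = 0.474), and immediate early genes (19 tested) one of 0.21 (adjusted p = 0.232). Kinase inhibitors and p53 targets (15 tested) had a median of 0.01 (adjusted p = 0.704), and apoptosis regulators (15 tested) one of -0.04 (adjusted p = 0.774). The stress lists lay near 0, with the unfolded protein response (20 tested) at 0.10 (adjusted p = 0.586), heat shock genes (12 tested) at -0.09 (adjusted p = 0.371) and autophagy and lysosome genes (20 tested) at -0.09 (adjusted p = 0.669).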

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

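The fits with array weights or with arrays left out, and the leave-one-out values of the ACTB and GAPDH ratios, were chosen after seeing the data. Against 0 genes higher and 0 genes lower in the tumor center, the counts became 42 and 16 with a pseudocount of 64, 72 and 36 with the upper-quartile filter, 94 and 41 with an intensity trend and robust prior, 8 and 2 with the mean of all probe sets, and 5 and 0 without _x_at and _s_at probe sets. They were 38 and 17 with no replicate block, 33 and 17 with no block and periphery 2 left out, 43 and 28 with no block and the 2 arrays of highest spike-in signal left out, and 240 and 181 with array weights. Those weights were equal for both arrays of a mouse (2.98, 0.347 and 0.968 for mice 1, 2 and 3), so they weighted whole mice and did not single out periphery 2; with mouse 2 left out altogether the counts were 0 and 0. Leaving out 1 mouse gave 0 to 12 genes higher and 0 to 1 lower. The counts stayed at 0 with a pseudocount of 1, no filter, quantile normalization, median centring and every probe set tested. Of the 55 genes called with no block, 55 were also called with array weights, 52 with the trend, 45 with the upper-quartile filter, 40 with a pseudocount of 64 and 37 without periphery 2. Gene lists higher in the tumor center numbered 6, and gene lists lower 5; both counts were 0 with an estimated correlation and with fry. Without _x_at and _s_at probe sets 2 lists were higher, and leaving out 1 mouse gave 5 to 6 lists higher and 3 to 6 lower. The lists of hypoxia, proteasome, mitosis and DNA replication genes kept their calls in every setting run except those with an estimated correlation and with fry. Without the block 6 lists were higher and 4 lower, and it ended the call of the mesenchymal list and of no other. The ACTB ratio difference ranged from 0.61 to 1.04 and the GAPDH one from -0.23 to 0.34 when 1 mouse was left out. Of the named genes, 7 reversed, none of them past the threshold where it did. KIF23 became 0.086 without _x_at and _s_at probe sets, where another probe set stands for it. Leaving out 1 mouse gave ranges of -0.309 to 0.148 for COL1A1, reversed without mouse 1 or 3, -0.399 to 0.874 for CTRC, reversed without mouse 1 or 3, and -0.467 to 0.289 for SST, reversed without mouse 2. They were -0.043 to 0.347 for CIDEC, reversed without mouse 3, -0.227 to 0.705 for EGFR, reversed without mouse 1 or 3, and -0.745 to 0.005 for MMP9, reversed without mouse 2. SST was 0.344 with array weights, 0.204 with no block and periphery 2 left out and 0.065 with no block and the 2 arrays left out, where EGFR was -0.324. Apart from the KIF23 probe set, the cause was not tested. Signal over background limits the dim genes, and periphery 2 had the highest median signal, 125, after scaling to the same trimmed mean.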

Other observations

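The tests of array brightness (read from spike-in signal), RNA integrity and host cells were chosen only after the results were seen. So was the count of splits at an unadjusted p. The genes of the next paragraphs were picked after their values were seen. Genes of TGF-beta signaling moved both ways. TGFBI, LTBP2 (-1.36 ± 0.24), INHBA (-1.05 ± 0.27) and PMEPA1 (-0.91 ± 0.26) were lower in the center and BAMBI, a decoy receptor of the pathway, was higher (1.58 ± 0.37), each in 3 of 3 mice and when adjusted over the list alone. The fry test for change in either direction gave this list and that of proteases and their inhibitors an adjusted p of 0.00577 each, but 22 of the 35 lists lay below 0.05 in that test. Among proteases and their inhibitors TIMP1, which blocks metalloproteases, differed by 1.56 ± 0.22 while MMP2 lay at -1.15 ± 0.22. THBS1, an inhibitor of angiogenesis, differed by -1.72 ± 0.31. Among apoptosis regulators PMAIP1 differed by -1.26 ± 0.26 and BCL2L11 by 0.93 ± 0.23, and the immediate early gene FOS by 1.80 ± 0.43.

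Outside the lists, 7 further genes picked by their small p were higher in the center of 3 of 3 mice without passing the threshold; no shared function was tested for them. The membrane protease TMPRSS4 differed by 3.01 ± 0.35 (adjusted p = 0.0815), the gel-forming mucin MUC5B by 2.91 ± 0.38, the secreted CHI3L1 by 2.66 ± 0.39, the cytokine IL33 by 2.40 ± 0.30 and the basal keratin KRT15 by 2.07 ± 0.31. IGFBP1, which like IGFBP3 binds insulin-like growth factors, differed by 1.73 ± 0.23, and PLAT, the tissue plasminogen activator, by 1.53 ± 0.22. The embryonic globin gene HBE1 was lower, at 85.8 ± 54.6 against 510 ± 93.1 (-2.53 ± 0.40).

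The upward shift of hypoxia-inducible genes (median 0.78) could come from array brightness, RNA integrity or the oxygen supply of the tumor center. Spike-in signal differed in mouse 2 by -2.91, opposite to mice 1 and 3, yet the list median in mouse 2 was 1.09 (SE 0.14), which argues against brightness as the whole cause. The ACTB ratio was higher in the center by 0.84 and in 3 of 3 mice, but the GAPDH ratio in 1 of 3, and the list median was highest in mouse 2, where the ACTB difference was smallest (0.45). With 3 mice and an integrity measure that moved with the zone, RNA integrity and zone cannot be told apart. A biological difference in oxygen supply stays open as a hypothesis and was not tested.

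The upward shift of ribosomal protein genes may follow array brightness. List medians of 0.86, -0.31 and 0.85 had the sign of the spike-in difference in each mouse. So did the 80 brightest genes other than ribosomal protein genes, with -0.22 (SE 0.09) in mouse 2 against 0.54 and 0.56. Quantile normalization took the list median to 0.11. The list median lay above that of the other bright genes in mice 1 and 3. In mouse 2 the list median of -0.31 (SE 0.15) and that of the other bright genes did not differ beyond their errors. Whether this excess follows the spike-in difference therefore cannot be told. The sizes did not follow it, since the largest spike-in difference (-2.91, mouse 2) went with the smallest list shift. A further difference between center and periphery was not tested.

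The lower signals of COL1A2, COL3A1, CSF1R and FCER1G in the center could come from fewer host cells there, since mouse transcripts may bind human probes. Of 18 fibroblast and macrophage markers tested, 8 were lower in 3 of 3 mice, 3 were higher in 3 of 3 and 7 were mixed. COL1A1, abundant in fibroblasts, differed by -0.05 ± 0.27, with its 3 other probe sets also lower (down to -0.74), and LUM, higher by 1.58 ± 0.38, moved the other way. Fewer host cells and lower expression in the tumor cells cannot be told apart for the 8 markers, because how well each human probe set reads the mouse transcript, and how much of each gene the tumor cells express, is not known from these values.

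The 6 arrays split into 3 and 3 in 10 ways, too few for a share under 0.05. At an adjusted p below 0.05 the real split gave 0 genes and the highest other split 0, so 10 of 10 splits gave as many; with no block the real split gave 55 and each other split 0. At an unadjusted p below 0.05 the real split gave 1385 genes and the highest other 1913, and 3 of 10 splits gave as many, the real one included. Both splits with 1913 part only the pair of mouse 2, which holds periphery 2, the array with the highest spike-in signal. With mouse as a block they are 1 fit with its sign reversed, so the count of 3 holds that fit 2 times. The other splits that part 1 pair repeat in the same way, so the 10 splits are fewer than 10 separate blocked fits. A blocked fit that parts 1 pair estimates the difference between center and periphery in that mouse alone. Such splits carry the real contrast, so their counts, the 1913 included, do not measure chance. Among splits that part all 3 pairs the highest other gave 755. For gene lists the real split gave 11, and 1 of 10 splits, the real one, gave as many. The highest other gave 10, again from splits that part 1 pair. Among splits that part all 3 pairs the highest other gave 4.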
